A study of Mus musculus with 16 samples.

How the data were processed

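RNA from 16 samples of stem-cell-enriched mouse haematopoietic cells was measured on Illumina bead arrays, 4 arrays for each combination of genotype and treatment. Per the labels, the mice were of C57BL/6 background, RNA was extracted with the PicoPure kit, amplified with the Illumina TotalPrep kit and labelled with biotin. The brightness of a probe follows the amount of its transcript.

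The table used for the main results holds, per the file headers, an average signal for each of 25697 probes on each array, an intensity on a linear scale, and the values show no normalization between arrays. Per the file headers the same table gives a detection p-value for each probe and array, small where the probe is brighter than the negative controls. The scanner software and any earlier background step are not given in the sources used here. A second deposited table holds intensity values that the authors processed. Judged from the values, they were quantile normalized between arrays on the linear scale without background subtraction, since each column held the ranks of its array's scanner values (rank correlation 1) and column medians lay close together. The steps behind them are not given either, and they served as an alternative only.

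Each array was placed in its group by the labels. Replicate numbers here only count the arrays of a group in the order of the series and pair nothing. The arrays lay on 2 slides, each holding 2 arrays of every group, so the slide could be fitted as a block and each comparison repeated within a slide.

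Intensities were background corrected with normexp, given an offset of 16, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3, with jsonlite 2.0.0 for the labels). Negative control probes were not used here, and neqc inferred the background from the detection p-values. A probe was kept where its detection p was under 0.05 on at least 4 arrays, which left 13374 probes. Gene symbols came from the deposited table. Against a table of current mouse genes of assembly GRCm38.p6, used only for names and for the order of genes along chromosomes, 17548 probes carried a current symbol, 7082 an older one that was updated, and 1046 one not in the table, which was kept as given. A further 21 probes whose symbols a spreadsheet had turned into dates were left out. The brightest passing probe stood for each gene, giving 9680 genes, of which 2585 had other passing probes. Among called genes 50 of 62 other probes had the same sign with interferon in WT cells and 628 of 695 in Jak2VF cells. Between genotypes it was 4 of 7 with vehicle and 778 of 813 with interferon.

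One linear model with 4 group means was fitted to all arrays with lmFit and eBayes (12 residual and 2.73 prior degrees of freedom), so that all groups shared one estimate of the spread. It gave interferon against vehicle in each genotype, Jak2VF against WT with each treatment, and the difference of the interferon changes. The p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes are limma's moderated test. Gene lists, 29 of them, were fixed by symbol and tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and with fry as alternatives. Fry tests whether the genes of a list move on balance one way, without comparing them with other genes. Counts of list members are given over all genes and adjusted over the list alone. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

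Named genes followed that rule. In each comparison they were the 8 with the largest positive and the 8 with the most negative log2 change among called genes whose groups of 4 arrays did not overlap and whose probe was detected on every array of the higher group, or the 5 largest called each way for the difference of changes. Up to 4 called members with the largest absolute change were added from each list described, or the member with the smallest p where none was called, and Jak2 and Ptprc always. Some genes that the rule selects are not reported here, while counts include them. Outside the rule, and chosen after their values were seen, were Ly6a and Uba7 with interferon in Jak2VF cells, the lower erythroid gene Nfe2, the remaining called genes of the difference (Abca3, Nxpe4 and Pla2g12a) and the haemoglobin genes Hba-a1 and Hbb-b1.

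The procedure was tested on simulated data with 9680 genes on 16 arrays and 200 changed genes. For interferon in WT cells it called 58% of genes changed by log2 1 and 88% of those changed by log2 2, for interferon in Jak2VF cells 62% and 92%, between genotypes 67% and 92% with vehicle and 53% and 88% with interferon, and for the difference 42% and 71%. Unchanged genes made up 5.81%, 4.94%, 4.22%, 2.08% and 7.38% of those calls.

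The alternatives were no background correction, median centring in place of quantile normalization, the authors' normalized values, no filter and a stricter filter on dim probes (detection p under 0.01 on 8 arrays), all probes tested singly, the slide as a fixed or random block and within each slide, array weights, a trended and robust variance model, a fit of only the groups compared, an adjusted p under 0.1, and leaving out each array in turn. Added after the data were seen were log2 mean brightness as a covariate, the omission of the 3 arrays with a mean intensity under 300 (WT vehicle replicates 1 and 3 and WT interferon replicate 2), list tests within slides and under median centring, and the slide, brightness, dim arrays and single arrays as alternatives for the Fisher test beside Ptprc, and list tests with an estimated correlation under the brightness covariate and without the 3 dimmest arrays. The number of arrays limits the precision of every value.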

Results

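Gene expression was measured on 16 Illumina mouse bead arrays hybridised with amplified RNA from cells enriched for haematopoietic stem cells, the rare marrow cells from which all blood lineages derive. The cells were either wild-type (WT), carrying the CD45.1 allele of the leukocyte surface protein CD45, or carried a knock-in of the activating Jak2 kinase variant found in polycythemia vera (Jak2VF) together with the CD45.2 allele. Mice received interferon alpha at 10000 units per day or vehicle for 4 weeks, which made 4 groups of 4 arrays. The series was made to learn what interferon alpha does to the stem cells that propagate this myeloproliferative neoplasm, a blood cancer with overproduction of red cells. The labels do not say that the arrays of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

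The arrays differed in brightness. Mean intensity per array was 305 ± 122 (SD, n = 4) with vehicle in WT cells, 498 ± 100 with vehicle in Jak2VF cells, 684 ± 305 with interferon in WT cells and 884 ± 218 with interferon in Jak2VF cells, and single arrays ran from 162 to 1130. The log2 difference in brightness was 1.13 for interferon in WT cells (exact two-sided permutation p = 0.0857, Benjamini-Hochberg 0.114 over 4 comparisons) and 0.81 in Jak2VF cells (0.0571, 0.114). Between genotypes it was 0.78 with vehicle (0.0857, 0.114) and 0.47 with interferon (0.371, 0.371), where the smallest p that 4 arrays against 4 allow is 0.0286. Between 8209 (31.9%) and 13055 (50.8%) of the 25697 probes were detected per array, both extremes lying in the WT groups. Correlations between arrays of one group ran from 0.900 to 0.985 with vehicle in WT cells and from 0.959 to 0.993 with interferon in WT cells, against 0.975 to 0.99 and 0.981 to 0.992 in Jak2VF cells. The first principal component held 48.1% of the variance and the second 17.9%.

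**Figure D1:**
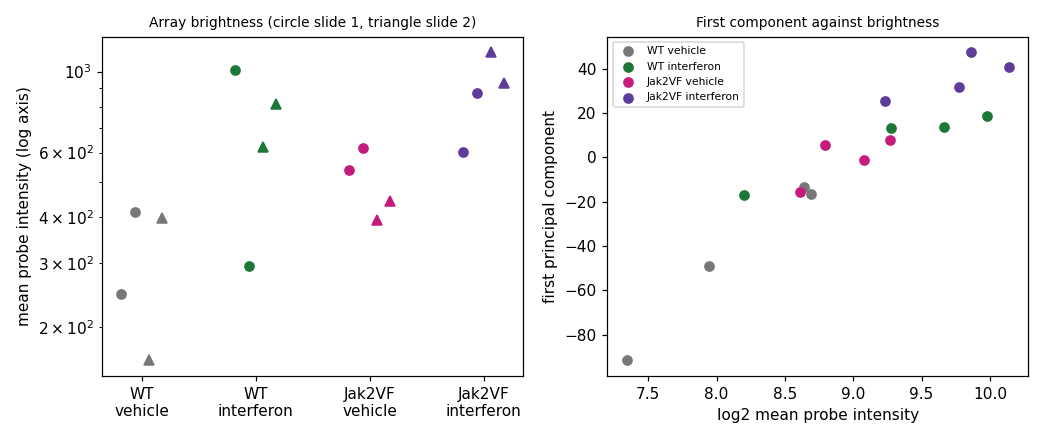
The left panel plots the mean intensity of each array on a log axis by group, with the marker showing the slide, and the right panel sets the first principal component against the log2 of that mean. Arrays ran from 162 to 1130, and within groups the component followed brightness (Pearson's r 0.855 over 16 arrays, permutation p = 0.00039).

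Jak2 and Ptprc, the gene of CD45, are altered in sequence and not deleted in these mice, so their levels check no label. Jak2 stood at log2 8.44 ± 0.09 (SD, n = 4) with vehicle in WT cells, 8.42 ± 0.31 with vehicle in Jak2VF cells, 9.15 ± 0.40 with interferon in WT cells and 8.95 ± 0.37 with interferon in Jak2VF cells. None of the 4 comparisons called it in limma (adjusted p = 0.0708 and 0.117 for interferon in WT and Jak2VF cells, 0.968 and 0.625 between genotypes with vehicle and interferon). The WT interferon value was 0.0177 without WT interferon replicate 2 and 0.047 without background correction. Ptprc was lower in Jak2VF cells with interferon, at a log2 difference of −0.55 (SE 0.17, adjusted p = 0.0325). That call was lost without WT interferon replicate 1 (0.0762) or 2 (0.0921) and without Jak2VF interferon replicate 3 (0.083) or 4 (0.115).

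With interferon in WT cells 7 of 49 antiviral and 4 of 37 red-cell genes rose. Of 6 B and plasma cell genes 2 fell. No list was called with an estimated correlation. Genes of eosinophil granules were among the largest falls, though the mast cell, basophil and eosinophil list fixed in advance was not called (0.221). Irf7, a transcription factor of the interferon response, rose by a log2 change of 2.66 (SE 0.35, adjusted p = 0.00202), Ifi27l2a, an interferon-inducible gene, by 2.82 (SE 0.46, 0.00645), and Usp18, which restrains interferon receptor signalling, by 1.21 (SE 0.11, 6.93e-05). Prg2, the eosinophil major basic protein, fell by 4.82 (SE 1.06, 0.0348) and Epx, the eosinophil peroxidase, fell by 3.90 (SE 0.48, 0.00138). Mzb1, a chaperone of antibody-secreting cells, fell by 4.41 (SE 0.38, 6.93e-05). Of 9680 genes tested with limma, 122 rose and 98 fell at adjusted p under 0.05, 220 in all, and 3081 had an unadjusted p under 0.05. Interferon arrays were brighter by log2 1.13.

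The 8 largest rises in WT cells included the actin-severing gene Scin (log2 change 3.44, SE 0.68, adjusted p = 0.0234), the pseudokinase gene Trib2 (2.68, SE 0.52, 0.0209), the erythroid gene Tspo2 (2.56, SE 0.37, 0.00293) and the tyrosine phosphatase gene Ptpn14 (2.36, SE 0.32, 0.00226). Capza1, which encodes an actin-capping subunit, and Atp1b2, a sodium pump subunit, were above background on no WT vehicle array and rose at least 2.82-fold and at least 2.94-fold (adjusted p = 0.00499 and 0.00138). Such a bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal detected on the array and the probe's own signal. It holds for these normalized values alone: under median centring the fitted log2 changes of Capza1 and Atp1b2 were 1.22 and 1.23, which lie below their bounds, and without background correction and in the authors' normalized values every change given here as a bound was smaller than it. Among the 8 largest falls were Prg3 (−4.10, SE 0.59, 0.00293) and the eosinophil ribonuclease genes Ear4 (−4.12, SE 0.56, 0.00226), Ear2 (−3.96, SE 0.59, 0.00341), Ear12 (−3.72, SE 0.59, 0.00601) and Ear10 (−3.61, SE 0.58, 0.00604). The Ear genes are near-identical copies, so which of them the probes read is uncertain. With log2 brightness as a covariate, chosen after the data were seen, 2 of the 16 remained called, Ifi27l2a and Mzb1. The other 14 kept a median share of 0.898 of their log2 change, from 0.584 in Trib2 to 1.11 in Prg2, while their median SE went from 0.54 to 0.65. Irf7, for one, stood at 2.86 (SE 0.46, 0.0596) with the covariate. Without the 3 dimmest arrays 15 were called, all but Prg2 (0.0993). Ear12, Mzb1 and Ptpn14 were above background on 1 of the 4 arrays of their dimmer group, Ear10 on 2, and Prg2, Prg3, Epx, Ear2, Ear4, Irf7, Scin, Trib2 and Tspo2 on 3.

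Of 49 measured interferon-stimulated genes, 7 rose and 0 fell (15 and 0 adjusted over the list alone), among them Oas2, a sensor of double-stranded RNA, at 1.71 (SE 0.25, adjusted p = 0.00293). The interferon-stimulated list shifted up with a camera adjusted p of 2.26e-05, and adjusted p = 0.149 with an estimated correlation. Its value was 2.23e-05 with the slide as a block, 6.4e-05 within slide 1 and 0.000819 within slide 2. Of 37 erythroid genes 4 rose and 0 fell (8 and 0 adjusted over the list alone), among them Tspo2, the water channel gene Aqp1 at 1.25 (SE 0.30, adjusted p = 0.0435) and Klf1, the master transcription factor of red cells, at 1.13 (SE 0.19, 0.00758). The erythroid list shifted up at 0.00943 (0.0116 with the block, 0.0781 and 0.0115 within slides 1 and 2), with adjusted p = 0.544 with an estimated correlation and 0.0843 under median centring. Among 28 Myc targets and ribosome biogenesis genes, the chaperonin gene Hspd1 rose at 0.75 (SE 0.16, 0.0321), with 1 higher and 0 lower (5 and 0 adjusted over the list alone). The Myc target list stood at 0.0325 (0.0305 with the block, 0.0544 and 0.22 within slides, adjusted p = 0.544 with an estimated correlation). Its call was lost without WT vehicle replicate 1 (0.0573) or 2 (0.0962) and without WT interferon replicate 4 (0.059).

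Among lists of mature blood cells, those of granulocytes and monocytes and of B and plasma cells moved down in WT cells. Among 27 granulocyte and monocyte genes 0 rose and 4 fell (0 and 6 adjusted over the list alone), and these were Ear2, the calprotectin genes S100a8 (−3.13, SE 0.66, adjusted p = 0.0315) and S100a9 (−3.22, SE 0.71, 0.0344), and Chil3 (−2.36, SE 0.52, 0.035). The granulocyte list stood at 0.000344 (0.000334 with the block, 9.23e-05 and 0.0115 within slides, adjusted p = 0.544 with an estimated correlation), and at 0.109 without the 3 dimmest arrays. Of 6 mature B and plasma cell markers 0 rose and 2 fell, also adjusted over the list alone, Mzb1 and Jchain, the joining chain of antibodies, which fell at least 3.50-fold (0.00638). The B and plasma cell list stood at 0.00198 (0.00208 with the block, 0.00412 and 0.0116 within slides, adjusted p = 0.181 with an estimated correlation). Of 13 mast cell, basophil and eosinophil markers 2 fell, Prg2 and Epx, and 0 rose (2 higher and 2 lower adjusted over the list alone), with a list adjusted p of 0.221, and 0.00644 with brightness as a covariate (there adjusted p = 0.337 with an estimated correlation). Among 9 MHC class II genes, which present antigen, H2-DMb1 fell at −0.98 (SE 0.18, 0.0148), with 0 higher and 1 lower (0 and 6 adjusted over the list alone). The class II list stood at 0.000575 (0.000506 with the block, 6.4e-05 and 0.0298 within slides, adjusted p = 0.544 with an estimated correlation). Of 35 haematopoietic stem cell genes 2 fell, among them Sult1a1 (−2.09, SE 0.45, 0.0335), and 0 rose (0 higher and 6 lower adjusted over the list alone). The stem cell list stood at 0.0301 (0.0296 with the block, 0.0781 and 0.0753 within slides, adjusted p = 0.544 with an estimated correlation). It lost its call under median centring (0.329), with no filter on dim probes (0.119) and without WT vehicle replicate 4 (0.0863).

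Interferon-inducible GTPases and guanylate-binding proteins, another class of interferon targets, had 0 of 10 members called in WT cells, 0 also adjusted over the list alone, and a list adjusted p of 0.221. The GTPase list was called downward with brightness as a covariate (7.55e-05), without the 3 dimmest arrays (0.0116) and without WT vehicle replicate 3 (0.0327). With an estimated correlation it was not called, at adjusted p = 0.673 with all arrays, 0.337 with brightness as a covariate and 0.598 without the 3 dimmest arrays. Their member with the smallest p, Gbp6, stood at −0.63 (SE 0.23, adjusted p = 0.0913), and at 0.0392 without WT interferon replicate 2. Oxidative phosphorylation genes shifted down as a list (0.00111, 0.0012 with the block, 0.0129 and 0.0115 within slides, adjusted p = 0.544 with an estimated correlation), though 0 of 42 were called over all genes and 3 higher and 7 lower adjusted over the list alone. That call was lost under median centring (0.0782), and with brightness as a covariate the direction turned (0.802). In all, 9 of 29 lists shifted, 3 up and 6 down, against 0 with an estimated correlation and 6 with fry.

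The WT count rested on single arrays, and fell to 1 when only the WT groups were fitted. It was 180 with the slide as a block. Within slides 1 and 2 it was 0 and 0 by limma (987 and 1678 at an unadjusted p under 0.05). Median centring gave 84 higher and 237 lower, of which 115 genes were among the 220. There Capza1 (adjusted p = 0.0508), Atp1b2, Aqp1 and Hspd1 (each 0.0503) lost their calls. Median centring also moved the median change of all genes to −0.14. Omitting in turn WT vehicle replicates 1 to 4 gave 47, 1134, 121 and 1609, and WT interferon replicates 1 to 4 gave 42, 1999, 47 and 44. Jak2VF vehicle replicates 2 and 4 gave 135 and 136, and Jak2VF interferon replicates 2 and 3 gave 93 and 101. Scin and Trib2 lost their calls without WT interferon replicate 1 (0.0853 and 0.0754), 3 (0.077 and 0.077) or 4 (0.0809 and 0.0693). Prg2 did so without WT vehicle replicate 1 (0.0947) or 3 (0.0663), WT interferon replicate 1 (0.0873), 3 (0.0705) or 4 (0.0618), or Jak2VF interferon replicate 3 (0.0516). H2-DMb1 was lost without WT vehicle replicate 1 (0.0544) and WT interferon replicates 1 (0.054) and 4 (0.0617), and S100a8 without WT vehicle replicates 1 (0.0931) and 3 (0.0548) and WT interferon replicates 1 (0.0754) and 3 (0.0902). Each of Aqp1, Chil3, Hspd1, S100a9 and Sult1a1 was lost without WT vehicle replicate 1 or 3 and without WT interferon replicate 1 or 3, at up to 0.129, 0.112, 0.102, 0.108 and 0.116, and in 12, 7, 6, 6 and 6 of the 16 omissions in all. Aqp1 was also lost with the slide as a block (0.0545). With no filter on dim probes Aqp1 (0.0661), Prg2 (0.055), Sult1a1 (0.0532), S100a9 (0.0543) and Chil3 (0.0549) were not called, nor were Sult1a1 (0.0824), S100a8 (0.101), S100a9 (0.123) and Chil3 (0.139) without the 3 dimmest arrays. With brightness as a covariate the count was 3, with 646 at an unadjusted p under 0.05. Without the 3 dimmest arrays it was 180, only 77 of them among the 220.

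In Jak2VF cells interferon alpha raised antiviral, red-cell and ribosome biogenesis genes, and lowered genes of stem cells, megakaryocytes, antigen presentation and eosinophil granules. Irf7 rose by a log2 change of 2.29 (SE 0.35, adjusted p = 0.00088) and Rhag, a red-cell membrane glycoprotein, by 2.58 (SE 0.38, 0.000681). Selp, the P-selectin gene, fell by 1.41 (SE 0.21, 0.000801) and Cd74, the invariant chain of MHC class II, fell by 2.55 (SE 0.37, 0.000656). Prg2 fell by 5.06 (SE 1.06, 0.00546) and Epx fell by 3.37 (SE 0.48, 0.000594). Of 9680 genes, 630 rose and 916 fell, 1546 in all, and 2897 had an unadjusted p under 0.05. Interferon arrays were brighter by log2 0.81.

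The 8 largest rises were in Sphk1, a sphingosine kinase gene (2.68, SE 0.47, adjusted p = 0.002), Tlcd4, Rhag, Aldh1a7 (2.55, SE 0.37, 0.000656), Paqr9 (2.50, SE 0.19, 9.72e-06), the metallothionein gene Mt2 (2.49, SE 0.37, 0.000801), Ifi27l2a (2.49, SE 0.46, 0.00247) and Crip2 (2.48, SE 0.47, 0.00307). Tlcd4 was above background on no vehicle array and rose at least 3.84-fold (0.000206). The 8 largest falls were in Prg2, Epx, Prg3 (−3.47, SE 0.59, 0.00158), Ear4 (−4.47, SE 0.56, 0.000404), Ear2 (−4.33, SE 0.59, 0.000475), Ear6 (−4.01, SE 0.45, 0.000215), Ear12 (−3.50, SE 0.59, 0.00154) and Mzb1, which fell at least 7.37-fold (0.000313). All 16 genes remained called with the slide as a block, with brightness as a covariate, without the 3 dimmest arrays and in each omission of 1 array. In their dimmer group Prg3, Ear4 and Ear12 were above background on 1 of 4 arrays, Epx, Ear2, Ear6, Aldh1a7 and Paqr9 on 2, and Prg2, Rhag and Mt2 on 3.

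**Figure D2:**
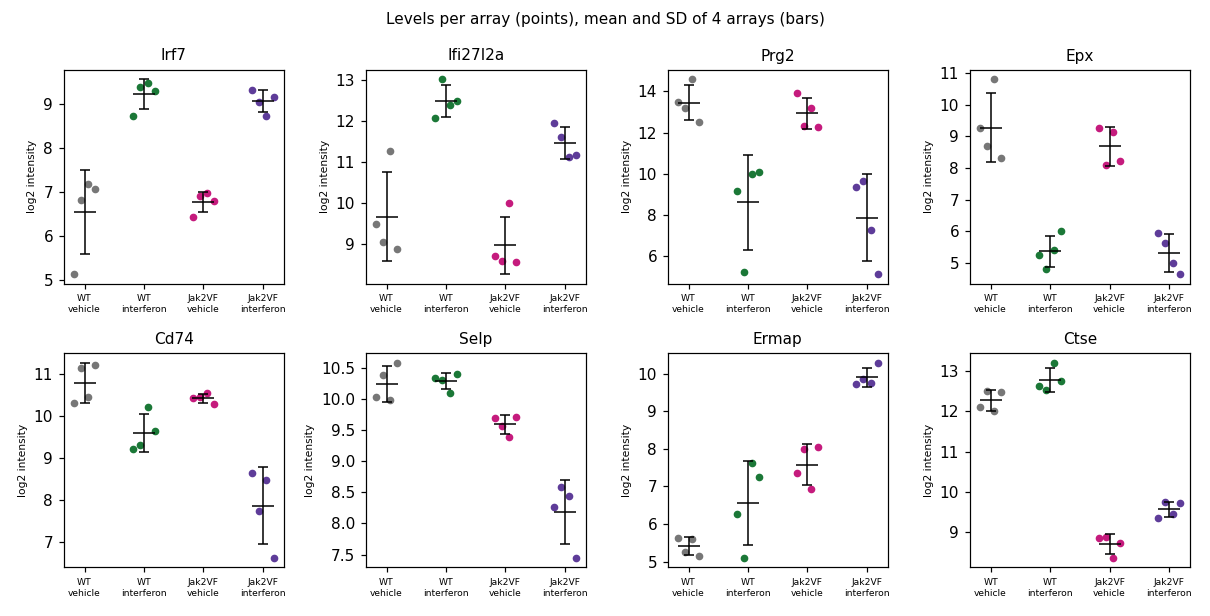
Normalized log2 intensity of 8 genes on each of the 16 arrays, by group, with the mean and SD of each group. Irf7 stood at 6.55 ± 0.95 and 6.77 ± 0.24 with vehicle and at 9.21 ± 0.34 and 9.05 ± 0.25 with interferon in WT and Jak2VF cells, and Selp at 10.29 ± 0.13 and 8.19 ± 0.51 with interferon.

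The interferon-stimulated list again shifted up, with 12 of 49 genes higher and 2 lower (12 and 3 adjusted over the list alone). Oasl1 rose at 2.22 (SE 0.26, adjusted p = 0.000249) and Oas2 at 1.57 (SE 0.25, 0.00098), while the stem cell antigen gene Ly6a fell at −0.75 (SE 0.20, 0.0224) and Uba7, the activating enzyme for ISG15 conjugation, at −0.65 (SE 0.17, 0.0189). The list stood at 0.000548 (0.000556 with the slide as a block, 2.53e-05 and 0.0129 within slides 1 and 2, adjusted p = 0.108 with an estimated correlation). The GTPase list went the other way, with 0 of 10 higher and 4 lower (0 and 6 adjusted over the list alone), among them Irgm2 (−1.47, SE 0.33, 0.00778) and the guanylate-binding protein gene Gbp2 (−0.91, SE 0.25, 0.0237). It stood at 0.013 (0.0154 with the block, 9.67e-05 and 0.21 within slides, adjusted p = 0.359 with an estimated correlation) and at 0.0561 under median centring. Of 9 MHC class II genes 0 rose and 8 fell (0 and 9 adjusted over the list alone), including H2-Eb1 (−2.62, SE 0.45, 0.00175), H2-Aa (−2.30, SE 0.30, 0.000405) and H2-DMb1 (−1.69, SE 0.18, 0.000158). The class II list stood at 2.22e-09 (2.95e-09 with the block, 1.28e-09 and 1.94e-06 within slides, adjusted p = 0.0898 with an estimated correlation). Mature B and plasma cell markers went down as well, with 0 of 6 higher and 3 lower (0 and 4 adjusted over the list alone), Mzb1 among them. That list stood at 0.00367 (0.00334 with the block, 0.0051 and 0.0082 within slides, adjusted p = 0.108 with an estimated correlation).

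Many red-cell genes rose in Jak2VF cells. Of 37 erythroid genes 19 rose and 0 fell, also adjusted over the list alone, led by Sphk1, Rhag, Mt2 and Ank1, the ankyrin of the red-cell skeleton (2.41, SE 0.42, adjusted p = 0.00178). The erythroid list stood at 2.22e-09 (2.95e-09 with the slide as a block, 1.42e-10 and 1.03e-06 within slides, adjusted p = 0.0674 with an estimated correlation). Of 20 heme and iron genes 6 rose and 0 fell, also adjusted over the list alone, among them the heme enzyme gene Cpox (1.13, SE 0.26, 0.0103) and the transferrin receptor gene Tfrc (1.0, SE 0.22, 0.00745). The heme list stood at 0.00119 (0.00109 with the block, 8.48e-05 and 0.0082 within slides, adjusted p = 0.14 with an estimated correlation), and Cpox alone lost its call under median centring (0.117). Of 28 Myc targets and ribosome biogenesis genes 16 rose and 0 fell (19 and 0 adjusted over the list alone), by small amounts: Wdr74 0.89 (SE 0.19, 0.00706), Hspd1 0.79 (SE 0.16, 0.00445), Rrp12 0.72 (SE 0.15, 0.00461) and Npm3 0.65 (SE 0.09, 0.000594). The Myc target list stood at 4.05e-10 (5.55e-10 with the block, 1.57e-09 and 2.13e-06 within slides, adjusted p = 0.0674 with an estimated correlation).

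Many genes of stem cells and megakaryocytes, the platelet precursors, fell. Of 35 stem cell genes 0 rose and 18 fell (1 and 21 adjusted over the list alone), among them the guidance receptor gene Robo4 (−2.29, SE 0.36, adjusted p = 0.00106), the adhesion gene Esam (−2.11, SE 0.34, 0.00114) and Cdkn1c, the cyclin-dependent kinase inhibitor p57 (−2.03, SE 0.50, 0.0136). The stem cell list stood at 2.22e-09 (2.25e-09 with the block, 1.42e-10 and 1.17e-06 within slides, adjusted p = 0.0674 with an estimated correlation). Of 27 megakaryocyte and platelet genes 0 rose and 13 fell, also adjusted over the list alone, including Selp, the transcription factor gene Fli1 (−1.58, SE 0.30, 0.00273) and the integrin gene Itga2b (−1.42, SE 0.22, 0.000947). The megakaryocyte list stood at 2.06e-05 (3.73e-06 with the block, 3.06e-05 and 7.16e-05 within slides, adjusted p = 0.33 with an estimated correlation). Granulocyte and monocyte genes had 0 of 27 higher and 6 lower (0 and 7 adjusted over the list alone), with Ear2, S100a9 (−2.60, SE 0.71, 0.0226), S100a8 (−2.43, SE 0.66, 0.0224) and the neutrophil protease gene Prtn3 (−1.54, SE 0.38, 0.0152). Of 13 mast cell, basophil and eosinophil markers 1 rose and 6 fell, also adjusted over the list alone, and that list stood at 0.00414 (0.00515 with the block, 0.000154 and 0.083 within slides, adjusted p = 0.201 with an estimated correlation). Of 10 mature T and NK cell markers 0 rose and 2 fell, also adjusted over the list alone. That list stood at 0.0367 (0.0314 with the block, 0.372 and 0.0115 within slides, adjusted p = 0.202 with an estimated correlation), and was not called with brightness as a covariate (0.286), with no filter (0.0623) or without Jak2VF vehicle replicate 3 (0.0709). The granulocyte list stood at 2.06e-05 (2.01e-05 with the block, 2.41e-08 and 0.00334 within slides, adjusted p = 0.28 with an estimated correlation).

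Targets of Jak-Stat signalling fell in Jak2VF cells, 7 of 27 against 0 higher (8 and 1 adjusted over the list alone). They included Socs3, a feedback inhibitor of the pathway (−1.49, SE 0.34, adjusted p = 0.0097), the cyclin gene Ccnd1 (−1.25, SE 0.21, 0.00129) and Stat3 (−1.02, SE 0.14, 0.000488). The Jak-Stat list stood at 0.00097 (0.000731 with the block, 9.67e-05 and 0.0129 within slides, adjusted p = 0.14 with an estimated correlation). Of 22 glycolysis and hypoxia genes 0 rose and 5 fell, also adjusted over the list alone, among them the glucose transporter gene Slc2a1 (−1.07, SE 0.15, 0.000475), but camera did not call the list (0.0688, within slides 0.00821 and 0.466), while fry called it downward (0.0139). In all, 18 of 29 lists shifted, 4 up and 14 down, against 0 with an estimated correlation and 19 with fry.

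The count in Jak2VF cells was 1484 with the slide as a block. Within slides 1 and 2 it was 9 and 2 (1172 and 2184 at an unadjusted p under 0.05). It fell to 962 and 941 without Jak2VF vehicle replicates 1 and 3 and to 712 without Jak2VF interferon replicate 4. Gbp2 lost its call without Jak2VF vehicle replicate 2 (0.0635) or 4 (0.0716), without Jak2VF interferon replicate 1 (0.0584) or 4 (0.0807) and under median centring (0.0729). S100a8 did so without Jak2VF vehicle replicate 1 (0.0723) or 3 (0.0534) and Jak2VF interferon replicate 3 (0.0536) or 4 (0.0597), S100a9 without Jak2VF vehicle replicate 1 (0.0739) or Jak2VF interferon replicate 4 (0.0633), and Prtn3 (0.0599) and Cdkn1c (0.0574) without Jak2VF interferon replicate 4. With brightness as a covariate the count was 1191, of which only 884 genes were among the 1546 of the main fit. Many calls were thus lost and others gained. S100a8 (−2.16, SE 0.78, 0.0896), S100a9 (−2.41, SE 0.85, 0.0809), Socs3 (−1.28, SE 0.40, 0.0512) and Ly6a (−0.69, SE 0.24, 0.077) kept most of their change, whereas Prtn3 (−1.16, SE 0.42, 0.0868) and Cdkn1c (−1.11, SE 0.35, 0.0525) shrank more. Without the 3 dimmest arrays, all from WT groups, the count was 3105.

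Of 9680 genes, 53 rose and 53 fell with interferon in both genotypes, 106 in all, against 17.2 for independent lists. Leaving out 1 array gave 30 to 591 shared genes and the brightness covariate 3. In opposite directions 1 gene was called. Across genes the 2 sets of log2 changes correlated at Pearson's r 0.56 and Spearman's rho 0.53, with genes not being independent replicates. These comparisons share no arrays but share each gene's spread, so are not independent.

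**Figure D3:**
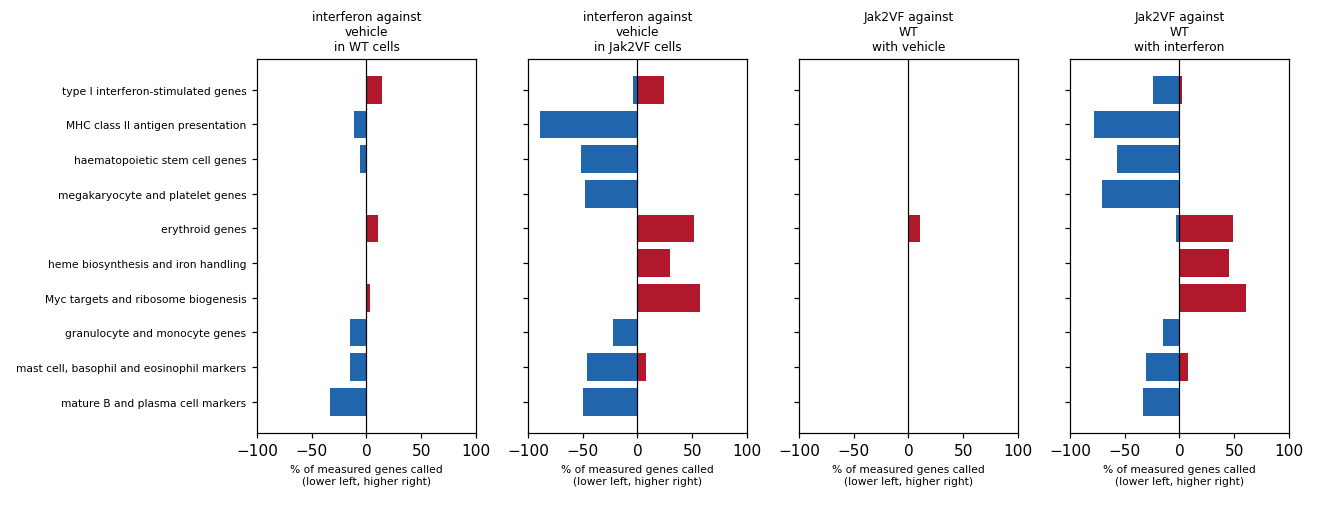
Percent of the measured members of 10 gene lists called higher and lower in each of the 4 comparisons. Of 37 erythroid genes 4 and 19 rose with interferon in WT and Jak2VF cells, and of 35 stem cell genes 2 and 18 fell.

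Without interferon, Jak2VF cells were set against WT cells. Of 37 erythroid genes 4 were higher in Jak2VF (list adjusted p = 0.317 with an estimated correlation). Genes near Ptprc, in a window chosen later, differed in either direction. Klf1 was higher by log2 1.21 (SE 0.19, adjusted p = 0.00985) and Tspo2 by 2.54 (SE 0.37, 0.00565). Ptpn7, a leukocyte phosphatase gene, was above background on no WT vehicle array and at least 16-fold higher in Jak2VF cells (7.97e-12). Ctse, the gene of cathepsin E, was lower by −3.56 (SE 0.18, 1.9e-08), with 12.27 ± 0.25 in WT and 8.72 ± 0.24 in Jak2VF cells (SD, n = 4). Of 9680 genes 30 were higher and 11 lower, 41 in all, and 2016 had an unadjusted p under 0.05. Jak2VF arrays were brighter by log2 0.78.

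The 8 largest positive differences with vehicle were in Ptpn7, the collagen gene Col5a1 (3.22, SE 0.47, adjusted p = 0.00565), the amino acid transporter gene Slc38a5 (2.56, SE 0.38, 0.00565), Tspo2, Sphk1 (2.48, SE 0.47, 0.0356), Atp1b2 (at least 2.75-fold, 0.00216), the erythroblast membrane gene Ermap (at least 3.19-fold, 0.0356) and Ptpn14 (1.80, SE 0.32, 0.0294). The 8 most negative were in Ctse, the chitinase-like gene Chil1 (−2.76, SE 0.37, 0.00303), Ptprv (−2.02, SE 0.18, 2.9e-05), Fhdc1 (−1.65, SE 0.21, 0.00216), Cxcr4, the receptor that retains stem cells in marrow (−1.47, SE 0.19, 0.00242), Sema6b (−1.22, SE 0.25, 0.0495), Pdcd4 (−1.16, SE 0.20, 0.0164) and Rab6b (−1.15, SE 0.20, 0.0225). With the slide as a block 15 of the 16 remained called, all but Sema6b (0.0681), with brightness as a covariate 12 did and without the 3 dimmest arrays 13, all but Ptpn14 (0.156), Sema6b (0.214) and Rab6b (0.0727). The 4 lost with the covariate kept most of their difference, Sphk1 at 2.09 (SE 0.52, 0.207), Ptpn14 at 1.65 (SE 0.38, 0.165), Sema6b at −0.95 (SE 0.25, 0.223) and Ermap with a share of 0.851 (0.207). In their dimmer group Chil1 and Ptpn14 were above background on 1 of 4 arrays, Col5a1 on 2, and Slc38a5, Tspo2 and Sphk1 on 3.

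Of 37 erythroid genes 4 were higher and 0 lower in Jak2VF cells (8 and 0 adjusted over the list alone), Tspo2, Sphk1, Ermap and Klf1. The erythroid list stood at 0.000699 (0.000553 with the slide as a block, 0.000101 and 0.00865 within slides 1 and 2, adjusted p = 0.317 with an estimated correlation). Heme and iron genes shifted up as a list (0.00135, 0.00127 with the block, 0.0207 and 0.00452 within slides, adjusted p = 0.317 with an estimated correlation) with 0 of 20 called over all genes and 4 higher adjusted over the list alone. Cpox had the smallest p among them (1.09, SE 0.26, 0.0909), and it was called without WT vehicle replicate 4 (0.0344), without WT interferon replicate 2 (0.00757) and without the 3 dimmest arrays (0.0437). Myc targets shifted up (7.44e-05, 7.56e-05 with the block, 0.00239 and 0.00393 within slides, adjusted p = 0.317 with an estimated correlation) with 0 of 28 called over all genes and 11 higher and 0 lower adjusted over the list alone. Their smallest p belonged to the spermidine synthase gene Srm (0.68, SE 0.17, 0.0993), which was called without WT vehicle replicate 2 (0.0445) or 4 (0.0344).

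The stem cell list was lower in Jak2VF cells (1.34e-06, 9.73e-07 with the block, 8.1e-05 and 6.02e-05 within slides, adjusted p = 0.317 with an estimated correlation). Of its 35 genes 0 were called over all genes and 8 lower adjusted over the list alone, and Sult1a1 had the smallest p (−2.13, SE 0.45, adjusted p = 0.061). Sult1a1 was called without WT vehicle replicates 2 (0.0171) and 4 (0.0418), Jak2VF vehicle replicate 3 (0.0114) or WT interferon replicate 2 (0.044), without background correction (0.0249) and in the authors' normalized values (0.0281). Megakaryocyte genes were lower as a list (0.000854, 0.000134 with the block, 8.75e-05 and 0.00426 within slides, adjusted p = 0.463 with an estimated correlation), with 0 of 27 called over all genes and 5 lower adjusted over the list alone. That megakaryocyte call was lost under median centring (0.0799) and without WT vehicle replicate 2 (0.053). The interferon-stimulated list was lower (0.00971, 0.01 with the block, 0.0247 and 0.099 within slides, adjusted p = 0.317 with an estimated correlation), with 0 of 49 called, 0 also adjusted over the list alone. Its call was lost under median centring (0.103), with no filter on dim probes (0.134) and without WT vehicle replicate 2 (0.0649) or 4 (0.0672). Granulocyte and monocyte genes were lower as a list (0.000699, 0.000553 with the block, 0.0127 and 0.000314 within slides, adjusted p = 0.409 with an estimated correlation) with 0 of 27 called, 0 also adjusted over the list alone, and stood at 0.421 without the 3 dimmest arrays and 0.0665 without WT vehicle replicate 1. In all, 12 of 29 lists differed, 6 higher and 6 lower, against 0 with an estimated correlation and 8 with fry.

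Some of the calls with vehicle lay beside Ptprc. Of 38 measured genes in the list of Ptprc neighbours 2 were called, Ptpn7 and the aminopeptidase gene Rnpep (1.80, SE 0.37, adjusted p = 0.0495), 5.26% against 0.404% of 9642 other genes (Fisher's exact two-sided p = 0.0112). That test hangs on Rnpep: with the slide as a block 1 was called (Fisher's exact p = 0.122), and without 1 array p ran from 0.00734 to 0.256, at or over 0.05 in 13 of the 16 omissions. It was 0.00221 with brightness as a covariate and 0.000707 without the 3 dimmest arrays. Adjusted over the list alone 6 were higher and 1 lower, and camera did not call the list (0.813, median −0.10, mean 0.18), while fry called it upward (0.00539). Within 100 tested genes either side of Ptprc, a window chosen after the values were seen, 6 of 201 were called with vehicle (Fisher's exact p = 0.000182): Cxcr4, Ctse, Chil1, Ptprv, Ptpn7 and Rnpep. All 6 were called in the same direction with interferon, Rnpep at 0.0295, lost in 7 of the 16 omissions at up to 0.072, with no filter (0.0509) and with brightness as a covariate (0.0535). The same window around Jak2 held 1 call of 201 (Fisher's exact p = 0.578). Each of the 6 genes was read by 1 passing probe.

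**Figure D4:**
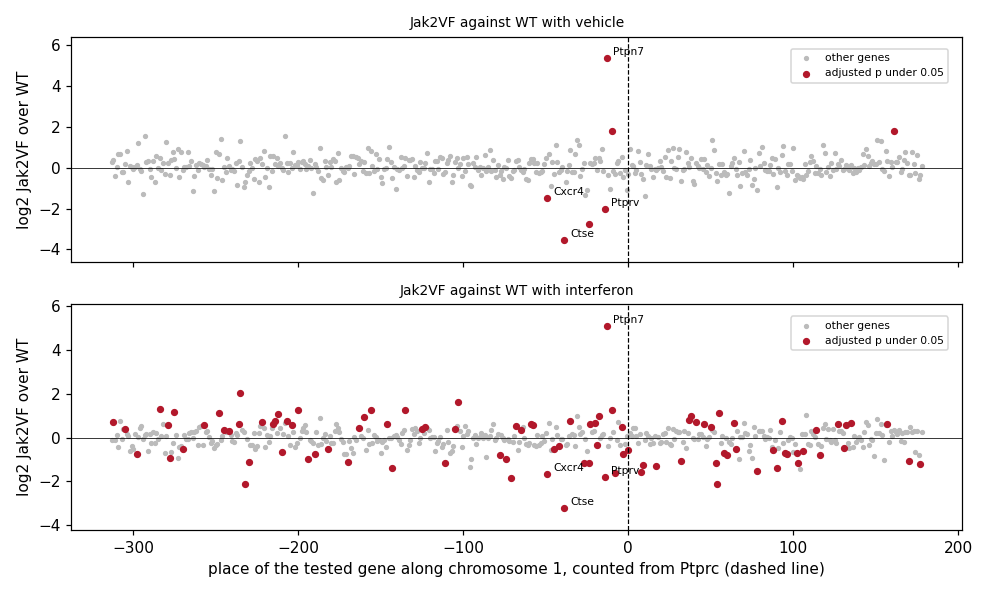
Log2 difference between Jak2VF and WT cells for the 492 tested genes of chromosome 1 in their order along it, counted from Ptprc, with vehicle and with interferon. With vehicle 7 of the 492 were called, 6 of them within 100 genes of Ptprc.

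The count with vehicle was 33 with the slide as a block, and 2 and 2 within slides 1 and 2 (947 and 742 at an unadjusted p under 0.05). Other scalings split the calls differently, into 24 higher and 17 lower without background correction, 21 and 13 in the authors' normalized values, and 10 and 9 under median centring. Omitting WT vehicle replicates 1, 2 and 4 gave 23, 249 and 404, Jak2VF vehicle replicates 1, 2 and 4 gave 24, 19 and 16, WT interferon replicates 2 and 4 gave 78 and 26, and Jak2VF interferon replicates 1, 2, 3 and 4 gave 26, 20, 23 and 25. Pdcd4 lost its call without WT vehicle replicate 1 (0.0583) or Jak2VF vehicle replicates 2 (0.0613) and 4 (0.0538), and Rab6b without WT vehicle replicate 1 (0.0635) or Jak2VF vehicle replicates 1 (0.0628) and 4 (0.0876). Ptpn14 did so without WT vehicle replicates 1 (0.0876) and 3 (0.0581), Jak2VF vehicle replicates 1 (0.0686), 2 (0.113) and 4 (0.106) or Jak2VF interferon replicate 2 (0.0508). Sphk1, Ermap, Sema6b and Rnpep were lost in 9, 10, 13 and 12 of the 16 omissions, at up to 0.136, 0.141, 0.156 and 0.141. With the slide as a block Rnpep was lost (0.0671). With no filter Rnpep (0.0773), Sphk1 (0.0579), Ermap (0.0582) and Sema6b (0.074) were not called. Sema6b was lost without background correction too (0.0604). Without Jak2VF vehicle replicates 1, 2 and 4 all 4 of these were lost. Under median centring the fitted log2 differences of Atp1b2, Ermap and Ptpn7 were 1.12, 1.15 and 3.83, below their bounds. There Tspo2 (0.0706), Atp1b2 (0.125), Ermap (0.128), Ptpn14 (0.193), Pdcd4 (0.112), Rab6b (0.0507) and Sema6b (0.0961) were not called. With brightness as a covariate the count was 18 and Klf1 stood at 1.06 (SE 0.20, 0.0637), and without the 3 dimmest arrays the count was 45. Of these 18 and 45 genes, 15 and 23 were among the 41 of the main fit.

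With interferon, red-cell, heme and Myc target lists were higher in Jak2VF than WT cells and stem cell, megakaryocyte and MHC class II lists lower. Only Myc target and stem cell lists were called with an estimated correlation. Eraf, the chaperone of free alpha globin, was higher by log2 3.54 (SE 0.45, adjusted p = 0.000195) and Tfrc by 2.06 (SE 0.22, 6.4e-05). Vwf, the von Willebrand factor gene, was lower by −1.94 (SE 0.27, 0.000337). Of 9680 genes 738 were higher and 979 lower, 1717 in all, and 2842 had an unadjusted p under 0.05. Median centring gave 1150 and 989.

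The 8 largest positive differences were in Ptpn7 (5.09, SE 0.15, 1.61e-11; detected on 1 of 4 WT interferon arrays), Sphk1 (3.61, SE 0.47, adjusted p = 0.000241), Slc38a5 (3.60, SE 0.38, 5.47e-05), Eraf, Ermap (3.35, SE 0.42, 0.000195), Crip2 (3.25, SE 0.47, 0.000406), Ank1 (3.05, SE 0.42, 0.000282) and Mt2 (3.03, SE 0.37, 0.000181). Among the 8 most negative were Ctse (−3.21, SE 0.18, 8.14e-08), Ndn, a growth suppressor gene (−2.29, SE 0.42, 0.0019), Selp (−2.11, SE 0.21, 4.21e-05), the caveola gene Cavin2 (−2.10, SE 0.23, 7.07e-05), Esam (−2.07, SE 0.34, 0.000922), Clu (−2.02, SE 0.38, 0.00225) and Fhl1 (−2.01, SE 0.36, 0.00155). All 16 remained called with the slide as a block, with brightness as a covariate, without the 3 dimmest arrays and in each omission of 1 array. Of the WT arrays, 2 of 4 detected Mt2 and 3 of 4 detected Ermap, Crip2 and Ank1.

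Of 37 erythroid genes 18 were higher and 1 lower (19 and 1 adjusted over the list alone), the lower one being the transcription factor gene Nfe2 (−0.65, SE 0.17, adjusted p = 0.0151), also used in megakaryocytes. The erythroid list stood at 4.03e-08 (4.52e-08 with the slide as a block, 1.33e-10 and 4.19e-06 within slides 1 and 2, adjusted p = 0.0832 with an estimated correlation). Heme and iron genes had 9 of 20 higher and 0 lower, also adjusted over the list alone, with Tfrc and Cpox (1.68, SE 0.26, 0.000639, detected on 1 of 4 WT arrays), and a list value of 2.77e-05 (2.64e-05 with the block, 3.47e-07 and 0.000351 within slides, adjusted p = 0.0832 with an estimated correlation). Of 28 Myc targets 17 were higher and 0 lower (24 and 0 adjusted over the list alone), including Rrp9 (0.96, SE 0.13, 0.000307), the pyrimidine synthesis gene Cad (0.90, SE 0.18, 0.00368) and Srm (0.78, SE 0.17, 0.0055). The Myc target list stood at 1.24e-12 (2.02e-12 with the block, 7.19e-09 and 1.06e-10 within slides), with adjusted p = 0.0363 with an estimated correlation.

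Stem cell genes were lower, 20 of 35 against 0 higher (25 and 0 adjusted over the list alone), with Esam, Fhl1 and Vwf among them. The stem cell list stood at 1.13e-12 (1.14e-12 with the block, 5.19e-12 and 6.6e-12 within slides), with adjusted p = 0.0363 with an estimated correlation. Lists of other cell types were lower too, each at 0.0391. Stromal and endothelial markers had 0 of 11 higher and 2 lower (0 and 3 adjusted over the list alone; 0.0374 with the block, 0.0543 and 0.0534 within slides, adjusted p = 0.176 with an estimated correlation). Mature T and NK cell markers had 0 of 10 higher and 2 lower, also adjusted over the list alone (0.0351, 0.31 and 0.00841, adjusted p = 0.216 with an estimated correlation). Mast cell, basophil and eosinophil markers had 1 of 13 higher and 4 lower, also adjusted over the list alone (0.0379, 0.207 and 0.0144, adjusted p = 0.301 with an estimated correlation). Leaving out 1 array ended these calls at up to 0.0723, 0.0713 and 0.108, and the T and NK list was not called with brightness as a covariate (0.148), without the 3 dimmest arrays (0.0513) or with no filter (0.102). Of 27 megakaryocyte and platelet genes 0 were higher and 19 lower (0 and 22 adjusted over the list alone), among them Selp, Cavin2 and Vwf, and the megakaryocyte list stood at 4.65e-14 (7.66e-16 with the block, 8.56e-16 and 6.43e-14 within slides, adjusted p = 0.165 with an estimated correlation). Of 9 MHC class II genes 0 were higher and 7 lower (0 and 8 adjusted over the list alone), among them Cd74 (−1.72, SE 0.37, adjusted p = 0.00504), H2-Aa (−1.59, SE 0.30, 0.0022) and H2-Eb1 (−1.64, SE 0.45, 0.021). The class II list stood at 1.16e-06 (1.25e-06 with the block, 7.84e-05 and 6.96e-07 within slides, adjusted p = 0.165 with an estimated correlation). H2-Eb1 lost its call without WT interferon replicates 2 (0.0521) and 3 (0.0567) and Jak2VF interferon replicate 4 (0.0783).

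Interferon-stimulated genes were lower in treated Jak2VF than in treated WT cells, 12 of 49 against 1 higher (13 and 1 adjusted over the list alone). Ly6a (−1.42, SE 0.20, adjusted p = 0.000369), Uba7 (−1.03, SE 0.17, 0.00096) and Usp18 (−0.93, SE 0.11, 0.000126) were lower and Oasl1 was higher (1.14, SE 0.26, 0.00698). The interferon-stimulated list stood at 0.00872 (0.00894 with the block, 0.0799 and 0.0024 within slides, adjusted p = 0.176 with an estimated correlation), and at 0.0635 under median centring. Of 27 Jak-Stat targets 1 was higher and 7 lower (1 and 10 adjusted over the list alone), among them Stat3 (−0.94, SE 0.14, 0.000449) and Ccnd1 (−1.43, SE 0.21, 0.000388). The Jak-Stat list stood at 0.00149 (0.00124 with the block, 0.00501 and 0.00174 within slides, adjusted p = 0.175 with an estimated correlation). Glycolysis and hypoxia genes had 1 of 22 higher and 6 lower, also adjusted over the list alone, with Ndrg1 (−1.41, SE 0.18, 0.000195), Slc2a1 (−1.08, SE 0.15, 0.00027) and the pyruvate kinase gene Pkm (−1.06, SE 0.17, 0.000651). The glycolysis list stood at 0.0324 (0.0305 with the block, 0.0266 and 0.104 within slides, adjusted p = 0.216 with an estimated correlation), and at 0.208 under median centring. In all, 22 of 29 lists differed, 7 higher and 15 lower, against 2 with an estimated correlation and 22 with fry.

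The count with interferon was 1681 with the slide as a block, and 70 and 5 within slides 1 and 2 (1639 and 1531 at an unadjusted p under 0.05), and fell to 1044 without Jak2VF interferon replicate 4. It was 2185 with brightness as a covariate and 2426 without the 3 dimmest arrays. The genotype comparisons shared 28 calls, 19 higher and 9 lower, against 3.40 for independent lists, with 0 in opposite directions. They too share spread but no arrays. Their log2 differences correlated across genes at Pearson's r 0.46 and Spearman's rho 0.45.

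Whether interferon changed the genotypes differently was tested as the difference of the changes. Relative to WT cells, interferon shifted the megakaryocyte, stem cell and MHC class II lists downward in Jak2VF cells and the erythroid and Myc target lists upward, none of them called with an estimated correlation (adjusted p from 0.26 to 0.289). In WT cells the megakaryocyte list pointed upward (0.0512, adjusted p = 0.673 with an estimated correlation). It was called upward there with the slide as a block (0.0335), within slide 1 (0.00238), under median centring (0.0144), without background correction (0.0206), in the authors' normalized values (0.0266) and with no filter (0.00184), but not within slide 2 (0.284), with brightness as a covariate (0.377) or without the 3 dimmest arrays (0.818). The erythroid difference was not called by fry (0.0987). Abcg4, a transporter gene, stood at a log2 change of 0.23 in WT cells and 2.13 in Jak2VF cells, a difference of 1.90 (SE 0.30, adjusted p = 0.0246), and Paqr9 at 0.60 and 2.50 (1.90, SE 0.27, 0.0142). Of 9680 genes 11 differed, 9 upward and 2 downward, and 1361 had an unadjusted p under 0.05. Those single-gene calls are few and hang on the arrays used.

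Among the 5 largest upward differences, Tlcd4 (2.92, SE 0.40, adjusted p = 0.0142), Sfrp4, which encodes a secreted Wnt antagonist (2.28, SE 0.26, 0.00338), and the Rh blood group gene Rhd (1.60, SE 0.28, 0.0422) were above background only on the 4 Jak2VF interferon arrays, so their fitted sizes depend on levels below background. Ggt5 differed downward (−1.33, SE 0.23, 0.0422), with 0.81 in WT and −0.52 in Jak2VF cells. All 7 genes that the rule selects here kept their direction within both slides. With the slide as a block 5 remained called, Rhd (0.0548) and Ggt5 (0.054) being lost, and all 7 did with brightness as a covariate. Without the 3 dimmest arrays 2 did, and under median centring none, Tlcd4 standing at 0.0515, Sfrp4 at 0.0526, Abcg4 and Paqr9 at 0.0515, Rhd at 0.121 and Ggt5 at 0.605. Tlcd4 and Sfrp4 kept their calls in every omission of 1 array and Paqr9 lost it without WT vehicle replicate 1 (0.0501). Abcg4, Rhd and Ggt5 were lost in 7, 13 and 12 of 16 omissions, at up to 0.0801, 0.106 and 0.106, all 3 without WT vehicle replicate 1 among them. Rhd and Ggt5 were also lost without background correction (0.0575 and 0.085), in the authors' normalized values (0.0587 and 0.0743) and with no filter (0.0572 and 0.0553).

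The megakaryocyte list differed downward (1.53e-10, 3.01e-12 with the slide as a block, 8.02e-09 and 1.4e-08 within slides 1 and 2, adjusted p = 0.289 with an estimated correlation), with 1 of 27 lower over all genes and 14 adjusted over the list alone. The stem cell list differed downward (3.33e-05, 2.49e-05 with the block, 0.000225 and 0.00029 within slides, adjusted p = 0.26 with an estimated correlation), with 1 of 35 lower and 7 adjusted over the list alone. For MHC class II genes the value was 0.000143 downward (0.000127 with the block, 0.0125 and 0.00029 within slides, adjusted p = 0.289 with an estimated correlation), with 0 of 9 called and 4 lower adjusted over the list alone. Erythroid genes differed upward (0.000149, 0.00014 with the block, 5.72e-05 and 0.0149 within slides, adjusted p = 0.263 with an estimated correlation), with 2 of 37 higher, Rhd and Add2 (1.22, SE 0.21, adjusted p = 0.0422), and 8 higher and 2 lower adjusted over the list alone. Add2 was lost with the slide as a block (0.0601), without background correction (0.0816), in the authors' normalized values (0.0732), under median centring (0.194), with no filter (0.0572), without the 3 dimmest arrays (0.102) and in 13 of 16 omissions, at up to 0.106. The Myc target list differed upward (1.63e-05, 1.86e-05 with the block, 0.00195 and 0.00029 within slides, adjusted p = 0.26 with an estimated correlation), with 0 of 28 called and 4 higher adjusted over the list alone. Glycolysis genes differed downward (0.000232, 0.000245 with the block, 0.000585 and 0.0257 within slides, adjusted p = 0.26 with an estimated correlation), with 0 of 22 called and 6 lower adjusted over the list alone, and Pkm nearest (−1.25, SE 0.24, 0.0579). Pkm was called without background correction (0.0189), in the authors' normalized values (0.023), with brightness as a covariate (0.0329) and without Jak2VF interferon replicate 3 (0.0299). The interferon-stimulated list was not shown to differ (0.512), though it was called in both genotypes.

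In all, 11 lists differed, 4 upward and 7 downward, against 0 with an estimated correlation and 6 with fry. The gene count was 11 with the slide as a block and 0 and 0 within slides by limma, where 596 and 576 genes had an unadjusted p under 0.05. Other scalings gave 40 upward and 51 downward without background correction, 25 and 37 in the authors' normalized values, and 1 and 0 under median centring, which moved the median difference of all genes to 0.10. Omitting WT vehicle replicates 1 and 2 gave 2 and 25, WT interferon replicates 1, 2, 3 and 4 gave 3, 6, 3 and 7, Jak2VF vehicle replicates 1 and 2 gave 6 and 6, and Jak2VF interferon replicate 1 gave 7. With brightness as a covariate the count was 22, and without the 3 dimmest arrays it was 2. Usp18 missed the threshold (−0.81, SE 0.15, adjusted p = 0.0579) and was called without background correction (0.0189), in the authors' normalized values (0.023) and with brightness as a covariate (0.0312).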

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

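The tests of explanations below were chosen only after the results were seen, apart from the counts over other splits of the arrays, whose rule was written before their results were seen.

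Genes of eosinophil granules (Prg2, Prg3, Epx, Ear2, Ear4, Ear6, Ear10 and Ear12, a set picked from the called genes) fell with interferon, by medians of −3.93 in WT and −3.75 in Jak2VF cells, and the mast cell, basophil and eosinophil list fixed in advance was called in Jak2VF cells (0.00414; adjusted p = 0.201 with an estimated correlation) and in WT cells only with the brightness covariate (0.00644, against 0.221; adjusted p = 0.337 with an estimated correlation). A loss of mature marrow cells of every kind cannot be told apart from a loss of these alone. The haemoglobin genes Hba-a1 (−0.02 and −0.57) and Hbb-b1 (−0.75 and −0.28) were not called, with a lowest 95% bound of −1.75. Red-cell genes rose with interferon, which could offset such a loss. S100a8 (−3.13 and −2.43), S100a9 (−3.22 and −2.60), Mzb1 and, in WT cells, Jchain fell too. The macrophage and dendritic cell list pointed upward (medians 0.30 and 0.25, camera 0.224 and 0.179). In WT cells with the covariate it stood at 0.0021 (adjusted p = 0.337 with an estimated correlation). Only 5 and 7 of its 15 members were detected on every vehicle array. Array brightness as the whole cause is argued against in Jak2VF cells, where the median with the covariate was −3.32 and 8 of 8 stayed called (median SE 0.58 before, 0.68 after), whereas in WT cells it was −3.47 with 0 of 8 called, the SE having grown from 0.58 to 0.75. Eosinophil-lineage cells or their RNA in the sorted fraction cannot be told apart from a change within the stem cells, since only 1 of the 8 genes stayed detected on at least 3 arrays of both interferon groups, too few to ask whether they fell by a common factor. Interferon itself may act on either, and near-identical Ear copies may share signal between probes.

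Genotype differences beside Ptprc, whose CD45 alleles mark the genotypes, may come from strain variants linked to those alleles, which cannot be told apart from other causes here. Of the list fixed in advance 2 of 38 genes were called with vehicle (Fisher's exact p = 0.0112), which hangs on Rnpep, as given above. With interferon 13 of 38 were called against 17.7% of others (Fisher's exact p = 0.0164, 0.0155 with the block, 0.0581 without the 3 dimmest arrays). Without 1 array p was 0.05 or more in 13 and 7 of 16 omissions. Brightness is argued against, since 5 of the 6 called genes near Ptprc stayed called with it as a covariate, all but Rnpep (1.39, adjusted p = 0.228). Sequence variants under single probes cannot be told apart from changed transcript levels, as 0 of the 6 genes had a second passing probe, and an effect of Jak2VF itself stays open.

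Array brightness may be a source of spread within groups, since the first principal component followed it there (Pearson's r 0.855, permutation p = 0.00039; Spearman's rho 0.871, 0.00116; 0.869 and 0.00418 without WT vehicle replicates 1 and 3). As the whole cause of the shift of the interferon-stimulated list in WT cells it is argued against, since the list mean rose by 0.52 (SE 0.07) without and 0.50 (SE 0.09) with brightness in the model, with a lower 95% bound of 0.30, and camera gave 5.63e-13 with the covariate (adjusted p = 0.0219 with an estimated correlation, against 0.149 without the covariate). For the 220 called genes as a whole it cannot be told apart from interferon, which came with brighter arrays: the 220 genes kept a median share of 0.695 of their change with the covariate, all 220 in the same direction, while their median change went from 1.14 to 0.76 and the median SE from 0.239 to 0.266, a smaller change and a wider error. A swap of WT interferon replicate 2 with a WT vehicle array is argued against, because its interferon-stimulated list lay 0.46 above the highest WT vehicle array (8.99, against 8.22 to 8.53 with vehicle). An effect of interferon on the amount of RNA per sample stays open and was not tested.

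Other splits of the same arrays were fitted for each count. With interferon in WT cells 3 of 35 splits called as many genes as the real one (220, highest other 1984), so chance could not be excluded, and the split with 1984 put the 3 dimmest arrays on one side, which points to a structure of the samples by brightness. With interferon in Jak2VF cells only the real split did (1546, highest other 0), as between genotypes with vehicle (41, highest other 9) and with interferon (1717, highest other 0). As 1 of 35 is the lowest share possible, chance is not excluded.

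For the difference of changes 6 of 100 labellings called as many (11, highest other 576), so chance could not be excluded, and 576 calls point to a structure of the samples. Among the called genes were Tlcd4 (2.92), Sfrp4 (2.28), Abcg4 and Paqr9 (both 1.90), Rhd (1.60), Add2 (1.22), and Ggt5 (−1.33), besides Nxpe4 (1.44, SE 0.22, limma adjusted p = 0.0165), Pla2g12a (1.37, SE 0.23, 0.0332) and Abca3 (1.04, SE 0.16, 0.0165), named because they were called. Lists differed for megakaryocyte (1.53e-10), Myc target (1.63e-05), stem cell (3.33e-05), MHC class II (0.000143), erythroid (0.000149) and glycolysis genes (0.000232), and none of these 6 was called with an estimated correlation (adjusted p = 0.26 to 0.289). Oxidative phosphorylation stood at 0.000149 (adjusted p = 0.474 with an estimated correlation, 0.000221 and 0.0885 within slides). Calls that hang on single arrays were MHC class I (0.0247, and 0.0618 without Jak2VF vehicle replicate 4, 0.0517 without WT vehicle replicate 1), lymphoid priming (0.0304, up to 0.0899 without WT vehicle replicate 4, and lost also without WT vehicle replicate 2, WT interferon replicate 2 or Jak2VF vehicle replicate 3), stromal markers (0.0334, 0.067 without WT vehicle replicate 4, and lost without WT vehicle replicate 2 or Jak2VF vehicle replicate 3) and heme genes (0.0358, up to 0.101 without WT vehicle replicate 2, lost in 7 omissions). With an estimated correlation these 4 stood at adjusted p = 0.474, 0.422, 0.26 and 0.422.

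Single arrays lay apart from the other 3 of their group by Dixon's test at 5% in 36 of 440 sets, where 22 are expected by chance, with the gap given as a share of the group's range. Most often this was Jak2VF vehicle replicate 1 (6 sets), WT interferon replicate 2 (5) and Jak2VF vehicle replicate 4 (4). On the first component WT interferon replicate 2 lay low (0.853), and on the second WT vehicle replicate 3 lay high (0.966) and WT interferon replicate 2 low (0.858). In WT vehicle arrays, replicate 1 was high in Atp1b2 (0.904) and Ptprv (0.938), 2 in Aldh1a7 (0.895) and 4 in Ank1 (0.889), and 3 was low in Trib2 (0.863). In WT interferon arrays, replicate 1 was low in Lsp1 (0.879) and Ly6a (0.858) and high in Ndrg1 (0.928), 2 was low in Aldh1a7 (0.981) and high in Cpox (0.943) and Esam (0.853), and 4 was high in Ear12 (0.842). In Jak2VF vehicle arrays, replicate 1 was high in Chil3 (0.881), Jchain (0.892), Pkm (0.844), Rnpep (0.91) and Tlcd4 (0.886) and low in Usp18 (0.837), 2 was high in H2-DMb1 (0.853), 3 was low in Abca3 (0.836) and high in Ifi27l2a (0.888), and 4 was high in Fli1 (0.916), Rhd (0.845) and Rrp9 (0.831) and low in Satb1 (0.838). In Jak2VF interferon arrays, replicate 1 was low in Scin (0.859), 2 high in Ear4 (0.891) and Prg3 (0.92), 3 high in Chil1 (0.909) and Trib2 (0.864) and low in Tspo2 (0.861), and 4 low in Robo4 (0.946) and Slc2a1 (0.88).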

How the results depend on the processing

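The brightness covariate, omission of the 3 dimmest arrays and other alternatives marked above as added later were chosen only after the results were seen. No paired analysis was possible because the labels carry no replicate numbers. Of named gene values under the alternatives, 6964 kept their side of the threshold, 844 kept direction but lost it and 124 passed it newly. A further 3 reversed. Lists gave 3587, 226, 101 and 1. Reversals of uncalled values are not counted. The correlation of interferon changes between genotypes, 0.56, ran from 0.47 with brightness as a covariate to 0.66 without the 3 dimmest arrays over 23 settings. Under median centring Nbn reversed with interferon in WT cells (−0.41, adjusted p = 0.337) and between genotypes with vehicle (−0.30, 0.507), as did P4ha1 with interferon in WT cells (−0.62, 0.253). Neither is named elsewhere. Oxidative phosphorylation reversed in WT cells with the brightness covariate (adjusted p = 0.802). For each of these reversals, and for each count below that moved, the cause was not tested, except that within a slide and without an array fewer arrays entered the fit.

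Counts of called genes are given here in the order interferon in WT cells, interferon in Jak2VF cells, genotype with vehicle, genotype with interferon and the difference of changes, where the settings used gave 220, 1546, 41, 1717 and 11, and 106 for genes called in both genotypes under interferon, the shared count. Without background correction the WT count became 798, the difference 91 and the shared count 313. Median centring gave 19 between genotypes with vehicle and 1 for the difference. The authors' normalized values gave 660 in WT cells, 62 for the difference and 258 shared. With no filter the WT count was 119, genotype with vehicle 27, the difference 7 and shared 57, over 17836 genes, and the stricter filter left 1 for the difference. Testing probes singly gave 430 in WT cells. Within slide 1 the 5 counts were 0, 9, 2, 70 and 0, and within slide 2 they were 0, 2, 2, 5 and 0, where each fit had 2 arrays per group. Array weights raised all 5, to 1930, 3105, 115, 3354 and 145. The trended and robust model gave 663 in WT cells and 87 for the difference. Fitting only the groups compared gave 1 in WT cells, 2617 in Jak2VF cells and 3 between genotypes with vehicle. At an adjusted p under 0.1 the WT count was 1794, genotype with vehicle 118 and the difference 130. With brightness as a covariate the WT count was 3, genotype with vehicle 18, the difference 22 and shared 3. Without the 3 dimmest arrays Jak2VF cells gave 3105 and the difference 2.

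Lists called with an estimated correlation numbered 0, 0, 0, 2 and 0 in the same order, against 9, 18, 12, 22 and 11. Fry called 6 for the difference, slide 1 alone called 13 between genotypes with interferon, slide 2 alone called 6 for the difference, and the brightness covariate 14 in WT cells. Leaving out each array in turn gave 42 to 1999, 712 to 2217, 16 to 404, 1044 to 2301 and 2 to 25 genes in that order, and 30 to 591 shared. For lists the ranges were 7 to 13, 15 to 20, 8 to 16, 18 to 22 and 8 to 13. Signal over background sets a limit, since 31.9% to 50.8% of probes were detected per array and genes such as Tlcd4, Sfrp4 and Rhd were above background in 1 group only, so that their changes depend on levels below it.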

Other observations

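Within-slide and median-centred list tests were added after the data were seen. Lymphoid priming genes, which mark the first steps towards lymphocytes, went down with interferon in Jak2VF cells, with 2 of 10 higher and 6 lower, also adjusted over the list alone. Among the lower ones were Lsp1 (log2 change −1.63, SE 0.26, limma adjusted p = 0.00114), Il12a (−1.58, SE 0.19, 0.000329), the chromatin organiser gene Satb1 (−1.43, SE 0.19, 0.00044) and the B cell receptor gene Cd79b (−1.35, SE 0.24, 0.00206). The lymphoid list stood at 0.00385 (0.00375 with the block, 0.00299 and 0.0155 within slides, 0.0133 under median centring, 0.0623 with no filter, 0.201 with an estimated correlation). Marker lists of B and plasma cells, Cd79b among them (0.00367), and T and NK cells (0.0367) fell too (0.108 and 0.202 with an estimated correlation).

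Of 34 DNA replication genes 5 were higher and 1 lower in treated Jak2VF than in treated WT cells (7 and 1 adjusted over the list alone). The cyclin gene Ccne1 stood at 2.10 (SE 0.40, limma adjusted p = 0.00255), the ribonucleotide reductase gene Rrm2 at 0.75 (SE 0.15, 0.00316) and Mcm10 at 0.62 (SE 0.12, 0.0032), while the clamp loader gene Rfc2 was lower (−0.55, SE 0.12, 0.00444, and 0.294 under median centring). The replication list stood at 0.00621 (0.00599 with the slide as a block, 0.065 and 0.00222 within slides, adjusted p = 0.216 with an estimated correlation).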
